A study of Mus musculus with 8 samples.

How the data were processed

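Guide counts were analysed for 8 libraries of a sorted CRISPR interference screen in mouse regulatory T cells. The labels give each library a biological replicate number from 1 to 4 and a technical replicate number of 1 or 2, and the 2 libraries of a biological number share a biosample. The authors deposited one table of raw counts per guide and library on mm10, per the text record paired with each table. The aligner, the counter and their versions are not given in the sources used here, nor is the sorted population of a library. How reads were assigned to guides could therefore not be checked.

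Guide intervals are 1-based and span 23 bp, a 20-nt protospacer and its PAM. All 404 targeting sequences matched the reference genome of the same build at their stated position next to an NGG, and each had 1 such match on the assembled chromosomes. Of the 40 non-targeting sequences, 0 matched. Positions were annotated with GENCODE genes of that build. Guides within 500 bp of a neighbour were joined into 10 regions.

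Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). The filter removed no guide and left 444. The technical contrast had the biosample as a block, and the test between biosamples had the technical number as a covariate. Fold values are library 1 over library 2. Ratios per biosample used log2 CPM with a prior count of 2. Regions of at least 3 guides were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Class abundance was the median log2(CPM + 1) of a class minus that of the non-targeting guides. Scaling to non-targeting guides set each library's factor from the summed counts of the 40 such guides.

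The named guides were chosen by a rule fixed before the data were examined. Among guides past an adjusted p of 0.05, up to 10 with the largest absolute log2 ratio in each direction that moved the same way in all 4 biosamples are named, and for the biosample test up to 10 with the largest range. Regions are named by smallest camera p, up to 10 per direction, and by the 5 highest and 5 lowest abundances. The 5 guides nearest to the Tnfrsf18 start (6 with a tie), the Tnfrsf18 and Tnfrsf4 start classes and targeted members of the gene lists are named always. The lists were the GITR locus, regulatory T cell identity, NF-kB and TNF receptor signalling, T cell receptor signalling, IL-2 and STAT signalling, T cell transcription factors and common essential genes.

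The pairing of libraries comes from the shared biosample in the labels. The deviations of the paired libraries from their group means correlated at 0.06, 0.07, -0.03 and 0.06 for biosamples 1 to 4. For biosamples 1, 3 and 4 the library 2 of another biosample correlated higher, at 0.098, 0.123 and 0.079. The counts therefore do not bear out the pairing, which rests on the labels. No 2 libraries agreed within counting noise: the chi-square per degree of freedom of a pair was at least 9.33.

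The tests were first run on simulated counts drawn at the real means and totals. With 200 of 444 guides changed both ways between technical libraries, edgeR called 23.5% of those changed 1.25-fold, 76.9% at 1.5-fold, 99.9% at 2-fold and 1.52% of unchanged guides. With 60 of the 444 guides raised and none lowered, 1.25 unchanged guides on average were called lower with TMM, 20.4 with totals and 0.55 with scaling to the non-targeting guides. The raised guides were picked at random and raised 1.25-fold to 4-fold, against up to 15.8-fold in the data. These averages therefore do not bound the false lower calls in the data. With 200 guides changed in 1 biosample, the test between biosamples called 39% at 1.5-fold and 92.5% at 2-fold. With the 28 guides of the promoter region raised by a log2 ratio of 0.3, camera called that region in 20 of 20 simulations and any other region in 0. In the data 3 regions, of 28, 44 and 87 guides, rose by mean log2 ratios of 1.16, 0.52 and 0.38. That setting was not simulated, so the 0 does not bear on regions called lower beside them. The biological coefficient of variation of the blocked fit was 17.1%. Counts come from amplified DNA without molecular identifiers, so counting error understates the error of a single library.

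Alternatives fixed beforehand were scaling by totals or by non-targeting guides, DESeq2 1.42.0, limma-voom, no filter, at least 50 counts in every library, fits without the block or the technical number, leaving out each biosample, an estimated correlation, fry, joining within 250 or 1000 bp, starts within 500 bp or 2 kb, other pseudocounts (10 CPM, or a prior count of 0.5), each technical library alone, means over guides, all guides as reference, and Spearman's rho. The text records were not used as data.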

Results

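The data came from a pooled CRISPR interference screen in activated mouse regulatory T cells, CD4-positive and CD25-positive lymphocytes that restrain immune responses. The cells carried dCas9-KRAB, a cutting-deficient Cas9 fused to a repressor domain, so that a guide RNA directs repression to the site it matches. The screen was read out after cell sorting, and the protocol's name refers to GITR, the costimulatory receptor encoded by Tnfrsf18. The tables gave a count for each of 444 guides in 8 libraries, which were technical libraries 1 and 2 of 4 biosamples. The labels used here do not say which sorted population a library came from, so the contrast is described throughout as library 1 against library 2. Total counts ran from 148577 to 199964 per library and averaged 179792 ± 17662 in libraries 1 and 181436 ± 22818 in libraries 2 (SD, n = 4 each). The lowest count of any guide in any library was 35, and no guide was at 0. All 4 biosamples carry one donor identifier in the labels. The p-values of single guides therefore measure the spread of the ratio of library 1 to library 2 over these biosamples, not over donors. In edgeR that spread is moderated with information from all guides.

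The library tiled 43.52 kb of chromosome 4 (mm10), from 155991530 to 156035049, with 404 targeting guides, and held 40 non-targeting guides. The targeting guides fell into 10 groups of neighbours, named here by the genes they cover. These included the B3galt6-Sdf4 starts (155991530 to 155993979, 78 guides), the end of Sdf4 with Tnfrsf4 (156012494 to 156016790, 98 guides), an upstream region (156021340 to 156022872, 44 guides), the Tnfrsf18 promoter region (156025885 to 156026698, 28 guides) and a downstream region (156030620 to 156034019, 87 guides). The upstream region lies over the start of the unclassified transcript Gm37090 and the last exon of the antisense transcript Gm16008. The downstream region lies beyond the end of Tnfrsf18 (156026164 to 156028895, plus strand) and spans the start of Gm16008.

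The first comparison asked which guides differed between technical libraries 1 and 2 of a biosample. Guides at the Tnfrsf18 promoter, in the upstream region and in the downstream region were more abundant in library 1, by up to 15.8-fold at the promoter. In the promoter region 16 of 28 guides were higher in library 1, in the upstream region 13 of 44 and in the downstream region 32 of 87. Of the guides outside these regions, 1 was higher, at 156008651 to 156008673, and it is named here after its value was seen. It lies in an exon of a retained-intron transcript of Sdf4 and in an intron of the coding transcripts that span it. In all, 62 guides were higher and 12 lower in edgeR's quasi-likelihood test with biosample as a block (adjusted p under 0.05), and each of the 74 moved the same way in 4 of 4 biosamples. The split between higher and lower depended on scaling. It was 62 to 12 with TMM, 72 to 1 with scaling to the non-targeting guides and 55 to 50 with scaling to totals. Against TMM, scaling to the non-targeting guides raised the median log2 ratio of all guides by 0.11, and scaling to totals moved it by -0.15. All 62 guides higher with TMM were also higher with scaling to the non-targeting guides, and 55 of them with scaling to totals.

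**Figure D1:**
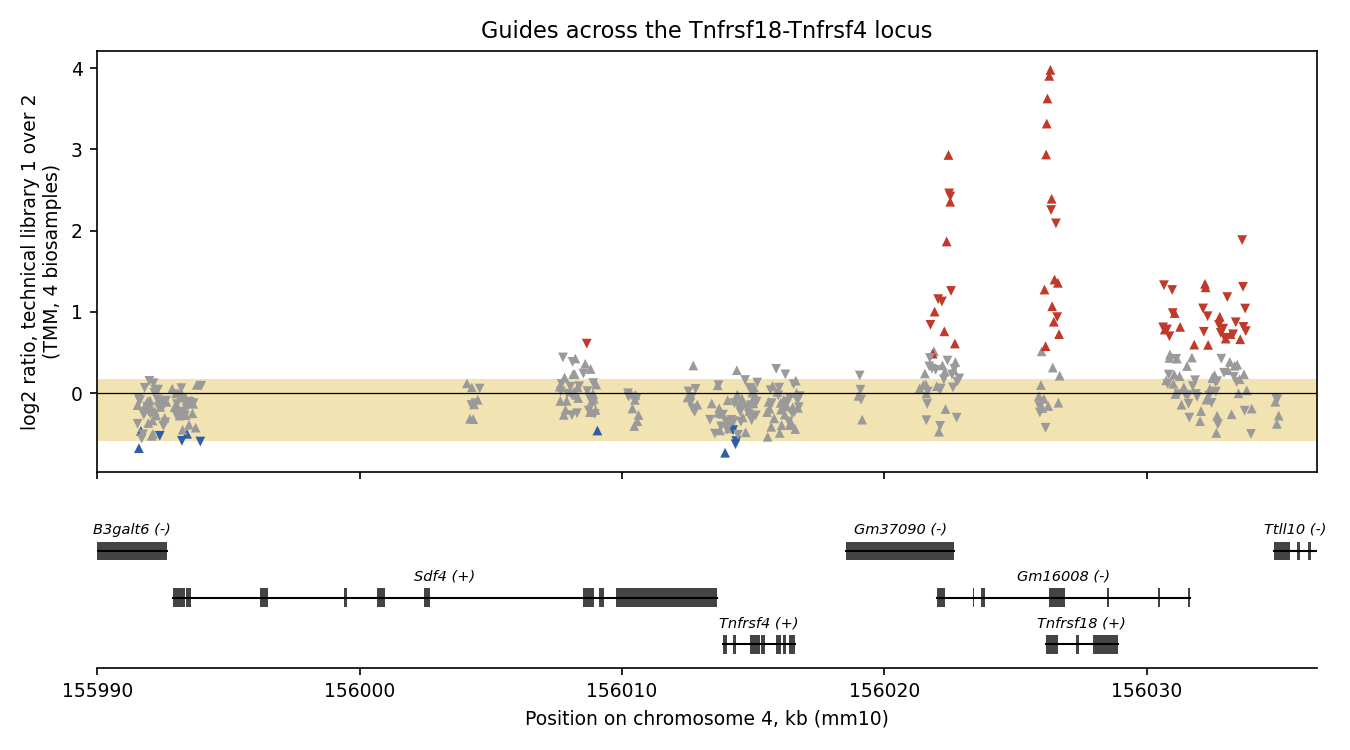
Each triangle is a targeting guide, placed by its position on chromosome 4 (kb, mm10) and its log2 ratio of library 1 over library 2 (TMM, 4 biosamples), pointing up for the plus and down for the minus strand, with gene models drawn below to scale. Red marks the 62 guides higher and blue the targeting guides lower in library 1 (edgeR, adjusted p under 0.05), the shaded band is the range of the 40 non-targeting guides (-0.58 to 0.16), and the red guides gather at and around Tnfrsf18.

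The guides with the largest ratios lay in the 5′ untranslated region of Tnfrsf18, as annotated from its first start at 156026164. Other coding transcripts start at 156026342, and several of these guides lie upstream of that start. The guide GAGACAAGGCAAGTTGGAGC (156026323 to 156026345, plus strand) had a mean count of 1540 ± 262 in libraries 1 and 111.5 ± 36.1 in libraries 2 (SD, n = 4), a log2 ratio of 3.98 ± 0.16 (SE; edgeR adjusted p = 1.69e-13). The guide GGCCTGAAGCCCAGTCTGAG (156026280 to 156026302) followed with a log2 ratio of 3.91 ± 0.17 (SE; edgeR adjusted p = 5.21e-13). TCTGCTCTACACTTCACAGA (156026211 to 156026233) reached 3.63, GTTAGGAGATGTCCAGAAAG (156026183 to 156026205) 3.32, GGAGTTGGGAGAGGCATGTA (156026160 to 156026182) 2.94 and ACTCAGGAGAAGCACTATGG (156026371 to 156026393) 2.39 on the log2 scale. The remaining 4 of the 10 highest guides lay in the upstream region, between 156022437 and 156022527, within the Gm37090 exon. Their log2 ratios were 2.93 for TACAGGAGCATTGTATCTCC, 2.46 for CAGACTGTTAATTAGCTCCA, 2.42 for CCTCTTGATATAGACTTGCA and 2.36 for CCTTGCAAGTCTATATCAAG. All 10 kept an edgeR adjusted p under 0.05 when any one biosample was left out.

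Of the guides nearest to the Tnfrsf18 start at 156026164, 6 because of a tie, 3 are among those 10 and 2 start at one position on opposite strands. The remaining one, CAGCAGTGGCACATGTGAAT (156026098 to 156026120, plus strand), had a log2 ratio of 1.27 ± 0.10 (SE; edgeR adjusted p = 9.97e-09). Of the 2 at one position, the plus-strand guide CCTAGCCAGGGCGAGTTTGC (156026139 to 156026161) had a log2 ratio of 0.58 ± 0.19 (SE; edgeR adjusted p = 0.0395), and it missed the threshold in 3 of the fits that left out a biosample. The minus-strand guide CCAGCAAACTCGCCCTGGCT had a log2 ratio of -0.43 ± 0.18 (SE; edgeR adjusted p = 0.118). With scaling to totals its log2 ratio was -0.58 and its adjusted p 0.03.

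**Figure D2:**
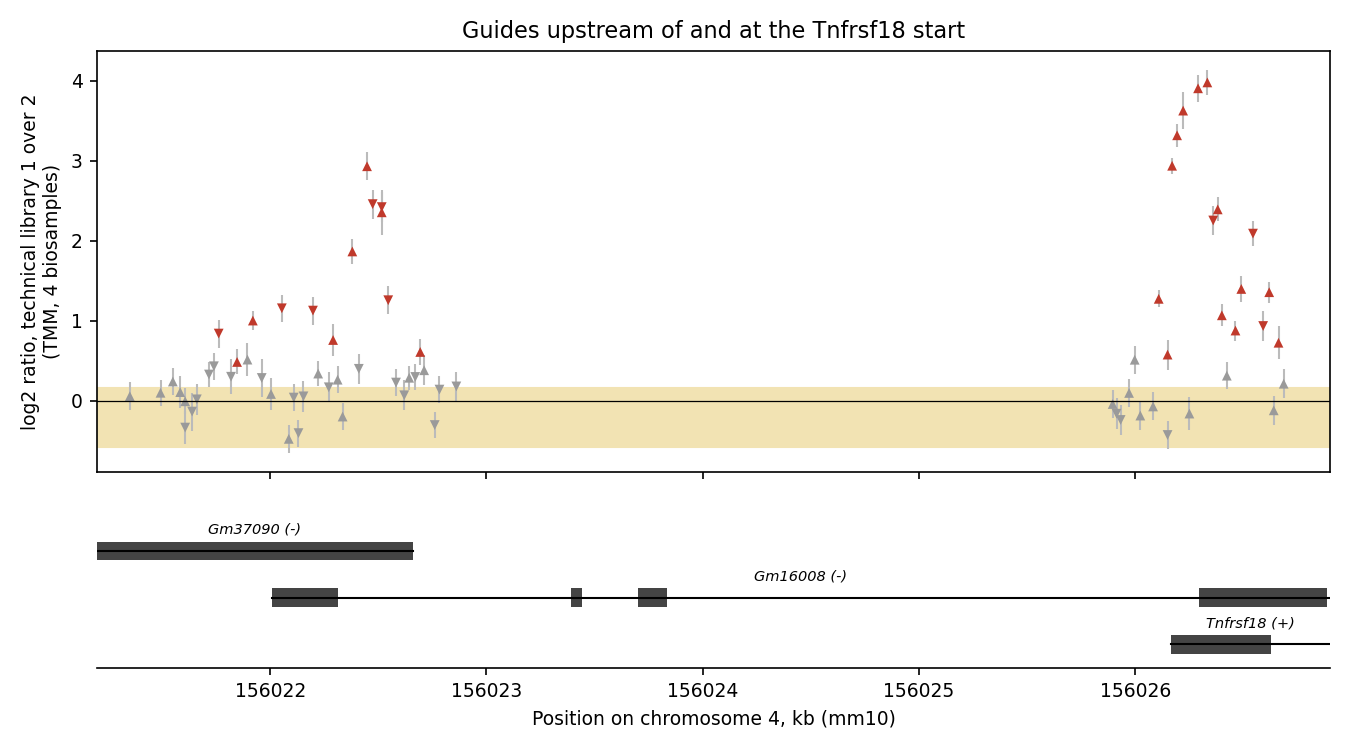
Log2 ratio of library 1 over library 2 (TMM, 4 biosamples) against position (kb, mm10) for guides of the upstream and promoter regions, with bars for the standard error and colours, triangles and shaded band as in the locus map. The highest ratio is 2.93 in the upstream region and 3.98 in the 5′ untranslated region of Tnfrsf18.

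Guides lower in library 1 changed less. The 12 lower calls comprised 6 guides at the B3galt6-Sdf4 starts, 4 in the Sdf4 end and Tnfrsf4 region, 1 in the body of Sdf4 and 1 non-targeting guide. The lowest ratio was that of CACTTGGAGTTACAGCAAGG (156013923 to 156013945) in the coding sequence of Tnfrsf4, the gene of the costimulatory receptor OX40, at -0.73 ± 0.18 (SE; edgeR adjusted p = 0.00514). It was also the 1 guide still lower with scaling to the non-targeting guides, at -0.63 and an adjusted p of 0.0116, but with TMM and without biosample 4 its adjusted p was 0.066. At the B3galt6-Sdf4 starts the log2 ratio was -0.68 for ATCAGATTGTTCAGGATGCT (155991580 to 155991602, B3galt6 3′ untranslated region), -0.47 for TTGCGCTGGCAGCACTGGGA (155991655 to 155991677) and -0.53 for TGGCTGGCACCGGAGAGGCG (155992375 to 155992397), both in the B3galt6 coding sequence. It was -0.59 for TAAGACAACCGGGAACGGTG (155993219 to 155993241) and -0.50 for TCTGAGCCGGCTCGACCCCG (155993414 to 155993436) in the Sdf4 5′ untranslated region, and -0.60 for TCCTCCAGCAACACAAAAAT (155993920 to 155993942) in an Sdf4 intron. In Tnfrsf4, GCACTGTGTACACTGCTTGC (156014321 to 156014343, coding sequence) had -0.63 and AGAGTAGGAAGGACTCACGA (156014346 to 156014368, intron) -0.59. The non-targeting guide TAGGGACGAGATTCGCTTTC had a log2 ratio of -0.58, and the median of all 40 non-targeting guides was -0.10 with TMM and -0.25 with scaling to totals. Each of these 10 lowest guides lost its call in at least 1 of the fits that left out a biosample. Without biosample 2 the lower calls numbered 3, and without biosample 4 they numbered 5.

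Gene classes were read from guides within 1 kb of a transcription start. Among the gene lists fixed beforehand, the list of the GITR locus had 4 of its 12 genes targeted and the other lists had none. Of the 28 guides at the Tnfrsf18 start, 16 were higher and 0 lower over all guides, and 17 higher and 1 lower adjusted over the list alone. Their mean log2 ratio was 1.16 ± 0.08 (SD, n = 4). Of the 39 guides at the Tnfrsf4 start, 0 were higher and 4 lower over all guides, and 0 higher and 1 lower adjusted over the list alone, with a mean log2 ratio of -0.27 ± 0.04 that was -0.16 ± 0.11 with scaling to the non-targeting guides (SD, n = 4). At the start of B3galt6, a galactosyltransferase gene, 2 of 38 guides were lower over all guides and 0 adjusted over the list alone. The mean log2 ratio was -0.21 ± 0.04, and -0.099 ± 0.073 with scaling to the non-targeting guides (SD, n = 4). At the start of Sdf4, which encodes a calcium-binding protein, 2 of 32 were lower over all guides and 0 adjusted over the list alone. The mean log2 ratio there was -0.18 ± 0.03, and -0.076 ± 0.090 with scaling to the non-targeting guides (SD, n = 4). With scaling to the non-targeting guides neither class held a lower call. The starts of Gm37090 and Gm16008, genes on none of the lists, also held guides higher over all guides, 13 of 37 and 15 of 49. Their mean log2 ratios were 0.61 ± 0.06 and 0.35 ± 0.09 (SD, n = 4).

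The second comparison asked whether the guides of a region moved together. The Tnfrsf18 promoter region had a mean log2 ratio of 1.16 ± 0.08, the upstream region 0.52 ± 0.06 and the downstream region 0.38 ± 0.07 (SD, n = 4). Relative to the non-targeting guides these were 1.26 ± 0.08, 0.62 ± 0.11 and 0.49 ± 0.12, or 2.40-fold, 1.54-fold and 1.40-fold. The limma camera test compares the guides of a region with the other guides, so its p-values rest on the spread between guides. It called the promoter (adjusted p = 6.15e-11), downstream (4.47e-08) and upstream (9.78e-06) regions higher than the other guides. It called the B3galt6-Sdf4 starts, at -0.20 ± 0.02, and the Sdf4 end with Tnfrsf4, at -0.18 ± 0.03 (SD, n = 4), lower than the other guides, both with a limma camera adjusted p of 4.19e-06. Relative to the non-targeting guides these 2 means were -0.094 ± 0.071 and -0.073 ± 0.088 (SD, n = 4), and both regions lay above 0 in biosample 2. Over the 4 biosamples the two-sided exact sign-flip p was 0.125, its lowest possible value, for each of the 5 called regions. All 5 calls held with an estimated correlation (adjusted p = 0.0243 each). With scaling to the non-targeting guides as well, none held: adjusted p = 0.0652 for the promoter and 0.156 for each of the others with an estimated correlation. The self-contained fry test of limma, with that scaling, called the promoter (adjusted p = 0.000656), upstream (0.00754) and downstream (0.012) regions and neither of the lower ones, at adjusted p = 0.157 for the B3galt6-Sdf4 starts and 0.33 for the Sdf4 end with Tnfrsf4.

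**Figure D3:**
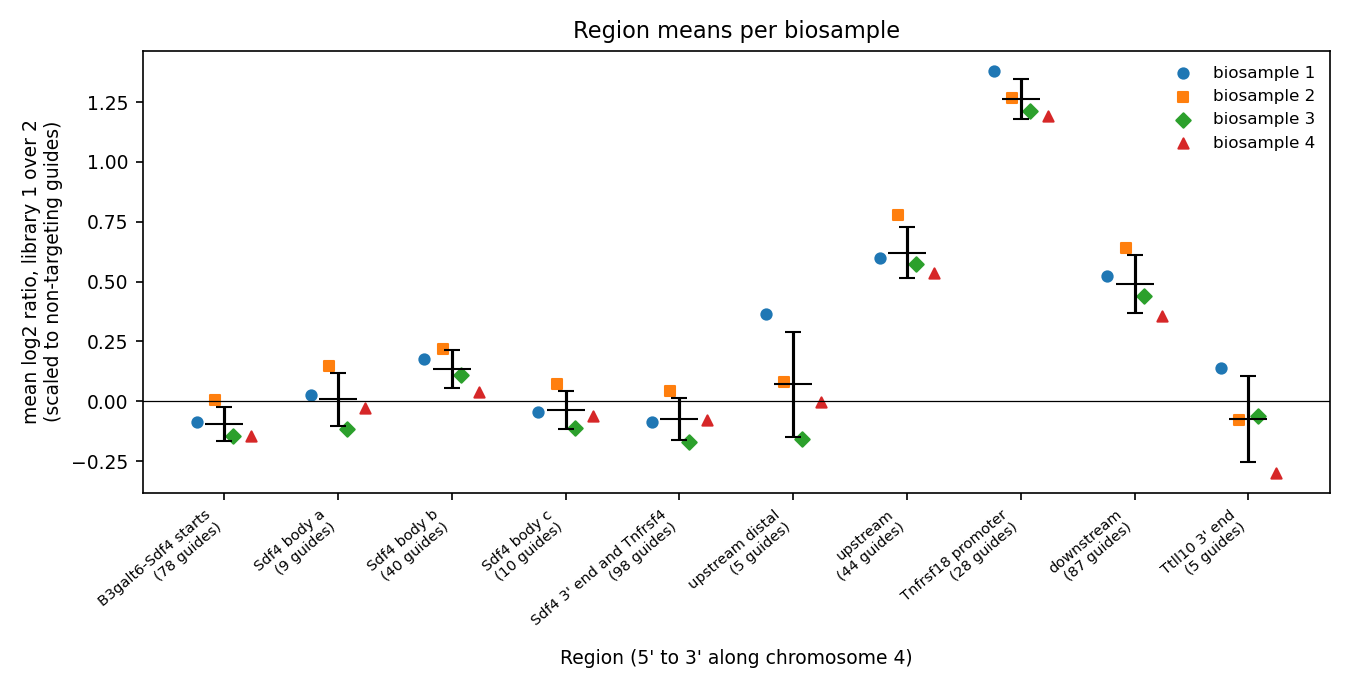
Mean log2 ratio of library 1 over library 2, scaled to the non-targeting guides, for the 10 regions in order along chromosome 4, with 1 point per biosample and black marks for the mean ± SD of the 4 biosamples. The upstream, Tnfrsf18 promoter and downstream regions, at means of 0.62, 1.26 and 0.49, lie above 0 in all 4 biosamples. So does 1 region in the body of Sdf4 (Sdf4 body b), at a lower mean of 0.14 ± 0.08.

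The third comparison asked whether libraries of one biosample resembled each other. They did so less than libraries sharing a technical number. Across guides, which are not independent replicates, Pearson's r of log2 CPM averaged 0.34 for the 4 pairs of one biosample and 0.811 for the 12 pairs of one technical number, with ranges of 0.306 to 0.395 and 0.773 to 0.853. The 12 pairs sharing neither averaged 0.331. Of the 105 ways to pair the 8 libraries, 86 gave a mean r at least as high as the pairing by biosample (exact permutation p = 0.819, one-sided), but 81 of the 105 hold at least 2 pairs of one technical number and are as high for that reason. Among the 24 pairings of a library 1 with a library 2, a set chosen after seeing the data, 5 were as high, the pairing by biosample included (exact permutation p = 0.208, one-sided). The 3 regions around Tnfrsf18 held 42.5 ± 0.7% of the counts in libraries 1 and 30.3 ± 0.5% in libraries 2, and the non-targeting guides 7.81 ± 0.19% and 9.33 ± 0.43% (SD, n = 4). Each of these differences had the same sign in 4 of 4 biosamples, for which 0.125 is the smallest two-sided exact sign-flip p.

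**Figure D4:**
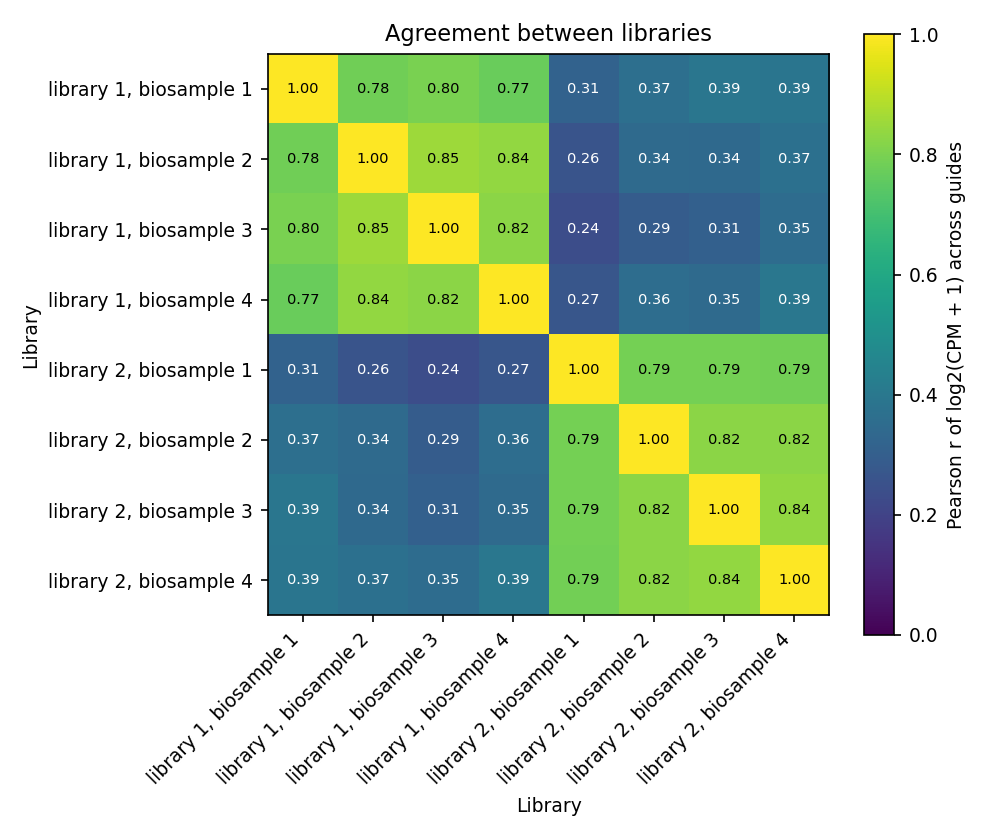
Pearson's r of log2(CPM + 1) across 444 guides for each pair of libraries, ordered by technical number and then biosample on both axes, with colour and printed value giving r. Pairs of one technical number lie between 0.773 and 0.853, and pairs of one biosample between 0.306 and 0.395.

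The fourth comparison asked whether guide abundance differed between biosamples. No guide did in edgeR's quasi-likelihood test with the technical number in the model (0 of 444, lowest adjusted p = 0.594). An unadjusted p under 0.05 was seen for 22 guides, where 22.2 were expected by chance. DESeq2 and limma-voom also called 0. The range of a guide's 4 biosample means had a median of 0.39 and reached 1.06 on the log2 scale.

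The last comparison set guide abundance at each class of site against the non-targeting guides, with both libraries of a biosample summed. No input library or opposite sorted fraction is labelled, so a difference in abundance is not enrichment. Guides at the Tnfrsf18 start lay 0.38 ± 0.10 above the non-targeting guides, guides at another start 0.08 ± 0.08 and all others 0.01 ± 0.08 (log2, SD, n = 4). The class at another start pools guides at the starts of B3galt6, Sdf4, Tnfrsf4, Gm37090 and Gm16008. For the Tnfrsf18 start the difference was 0.66 ± 0.13 in libraries 1 and -0.23 ± 0.06 in libraries 2, for another start 0.11 ± 0.06 and 0.0085 ± 0.0881, and for all others 0.05 ± 0.04 and -0.05 ± 0.09. With one biosample left out, the summed value for another start lay between 0.037 and 0.097. With 4 biosamples the two-sided exact sign-flip p cannot fall below 0.125. By region, with both libraries summed, the mean log2 CPM was highest at the Tnfrsf18 promoter (11.40), followed by a small distal upstream region (11.23), the B3galt6-Sdf4 starts (11.10), the upstream region (11.06) and 1 of the regions in the body of Sdf4 (11.04). It was lowest in the downstream region (10.95), at the end of Ttll10 (10.96) and in another part of Sdf4 (10.97), with 11.02 both at the Sdf4 end with Tnfrsf4 and in the last of the Sdf4 regions. This order depended on the library: the promoter ranked first of the 10 regions in libraries 1 (11.69 ± 0.03) and last in libraries 2 (10.67 ± 0.07), where the distal upstream region was highest (11.31 ± 0.06; SD, n = 4). Single non-targeting guides, both libraries summed, ranged from 10.18 to 11.89.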

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

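In 1 of 57 sets of 4 values tested for a value far from the others, library 1 of biosample 1 stood apart: its guide counts were less even, with a Gini coefficient of 0.268, against a lowest value of 0.239 among libraries 1. Chance flags about 1 set in 20, or 2.85 of 57.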

How the results depend on the processing

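Scaling to totals of the guides outside the 3 regions around Tnfrsf18, the GC correction, and both control and total scaling of the region tests were chosen after seeing the data. The count of guides lower in library 1 was 12, but 50 with scaling to totals, 1 with scaling to non-targeting guides, 1 with the totals of guides outside the 3 regions, and 3 to 14 with one biosample left out. The cause in the latter fits was not tested beyond their fewer samples. Higher calls ranged from 50 to 68 with one biosample left out. Without the replicate block 77 guides were called against 74, and 1 named guide lost its call there. Regions called numbered 5, and 7 with fry, which added 2 Sdf4 regions lower in library 1, but 0 with scaling to non-targeting guides and an estimated correlation, and 3 with that scaling and fry, for which the cause was not tested. Regions not called by the main test changed sign: one Sdf4 region, which fry with TMM called lower, went from -0.098 to 0.0081 and the distal upstream region from -0.036 to 0.070 with scaling to non-targeting guides under each of the 3 region tests, the distal region lay between -0.126 and 0.0113 with one biosample left out, and a second Sdf4 region went from 0.03 to -0.12 with totals. Abundance at the Tnfrsf18 start was 0.38, and 0.66 in library 1 or -0.23 in library 2 alone. Away from any start it was 0.013, between -0.023 and 0.043 with one biosample left out. Spearman's rho averaged 0.457 for pairs of one biosample and 0.779 for pairs of one technical number. Among named guides, 246 refits kept direction and side of the threshold, 51 lost the call and 1 gained it. At these totals, of 148577 counts or more, the smallest simulated changes were mostly missed.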

Other observations

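Within the regions, in windows of 200 bp set after seeing the data and the rise was uneven. Window means are relative to the non-targeting guides, and calls and ratios of single guides are those with TMM. In the upstream region it centred on 156022401 to 156022600, where 5 of 7 guides were higher in library 1 with a mean log2 ratio of 1.83 ± 0.14 (SD, n = 4), and the window just downstream, 156022601 to 156022800, averaged 0.32 ± 0.22. At the promoter the window 156026201 to 156026400 averaged 2.54 ± 0.30 with 6 of 7 guides higher. The exception there was the plus-strand guide at 156026240 to 156026262, between guides with log2 ratios of 3.63 and 3.91, at -0.16 (edgeR adjusted p = 0.713). The downstream region had several maxima, at 156030601 to 156030800 (0.87 ± 0.17), 156032201 to 156032400 (0.78 ± 0.39) and 156033601 to 156033800 (0.93 ± 0.12), with 0.13 ± 0.29 at 156031601 to 156031800 in between (SD, n = 4). Its highest guide, GGTCACAGAGGAAATGATCG at 156033633 to 156033655, is intergenic and had a log2 ratio of 1.88 ± 0.18 (SE; edgeR adjusted p = 1.09e-07).

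All tests below were chosen after the results had been seen, the bound on GC content and its limits when that bound was known in part. The first pattern is the rise of guides around Tnfrsf18 in library 1. Noise between repeat libraries would not recur across biosamples. Guides called higher in 3 biosamples had a median log2 ratio of 1.04 or more in the one left out (relative to the non-targeting guides, SD of the 4 medians 0.12). This argues against libraries 1 and 2 being repeats of one material that differ only by such noise. The GC slope of the guides outside the 3 regions, near 0, gave no guide inside them a log2 ratio beyond 0.11 even at 2 SE beyond its estimate. Against region means of 0.38 to 1.16 with TMM, that bound argues against a linear GC trend. The real split was the 1 of 35 splits of the 8 libraries with as many calls without the block (77, highest other split 1). That is the lowest share these splits can give, and the fit ignores the pairing, so chance is not excluded for the paired design. The 8 splits that part every pair, as the design does, are too few for a share under 0.05. Among them the real split, with 74 calls, was the 1 with as many, and the highest other had 0. Whether the technical number marks sorted fractions that differ in GITR was not tested, since the labels used here name no fraction, and no library was assigned to one.

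The second pattern is that non-targeting and distant guides lay lower in library 1 with scaling to totals. The median of the non-targeting guides was -0.25. Shares of a total alone cannot tell a rise of guides in the 3 regions from a common fall of all others, so this stays open. If the non-targeting guides are taken as unchanged, the narrower question has an answer. Relative to them the 3 regions averaged 0.49 to 1.26, and the regions outside averaged between -0.094 and 0.14. A property of non-targeting guides as a class is argued against, since they differed from the targeting guides outside the 3 regions by 0.023 (95% bootstrap interval -0.03 to 0.09). No biological explanation was tested.

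The third pattern is the rise in the downstream region, 4.456 to 7.855 kb beyond the Tnfrsf18 start. Repression spreading from a guide's site to the promoter would weaken with distance. Spearman's rho of log2 ratio with distance across the region's guides was -0.028 (95% bootstrap interval -0.24 to 0.19), which argues against a fall across the whole region. The region's 6 windows nearest the promoter did fall in order, from 0.87 to 0.13, so spreading over that part stays open. Nearer the start, the window 156025801 to 156026000 averaged 0.14 ± 0.22 with 0 of 5 guides higher. The window 156026601 to 156026800 averaged 0.65 ± 0.15 (SD, n = 4). The first of these lies below the 0.87 ± 0.17 at 156030601 to 156030800, which argues against distance from the start alone setting the ratio. No guides lay between 0.534 and 4.456 kb, so that stretch was not covered. Near matches of these guides elsewhere in the genome were not examined, and a regulatory element in the region was not tested.

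Whether strand matters could not be settled. Plus-strand guides of the promoter region had a mean log2 ratio of 1.27 (22 guides) and minus-strand guides 0.74 (6 guides), a difference of 0.53 ± 0.58 (SE; permutation p = 0.416, two-sided). At 11 positions with guides on both strands, the strands' log2 ratios had a Spearman's rho of 0 (95% bootstrap interval -0.83 to 0.73; permutation p = 1) and a Pearson's r of 0.862 (permutation p = 0.0375, both two-sided and across positions, which are not independent replicates). Without the 2 pairs farthest from the median, r was 0.475, so r rests largely on those pairs, and whether position sets the effect stays open.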
